A study of Mus musculus with 14 samples.

How the data were processed

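RNA-seq was measured in mESC, MEF, KD_control and Dppa5a_KD, and RNA immunoprecipitation (RIP) in IgG_RIP, Flag_RIP and HU_Flag_RIP, with 2 libraries in each of the 7 groups. Per the labels, RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit. Whether strand was kept is not given in the sources used here, so overlapping and antisense genes cannot be told apart. The authors deposited gene-level FPKM for the RNA-seq libraries, with lower and upper confidence bounds of the same unit, per the file headers. They deposited raw read counts per gene symbol for the RIP libraries, as the whole-number values in the deposited tables show. The genome build was mm10, and the submitters' processing notes name CASAVA 2.19, TopHat2 2.0.8, Cufflinks 2.1.1, Cuffdiff 2.1.1 and HTSeq 0.6.1, without saying what each was used for. No genome sequence was used here, and gene coordinates are those of the deposited tables.

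The FPKM tables held 24346 gene symbols at 24883 loci; 280 symbols had several loci, and 1 gene was marked as failed and left out. The FPKM summed to between 447657 and 585678 per library, and effective fragments estimated from the confidence bounds lay between 18332625 and 25337449.5. Of the 24421 gene symbols in the count tables, 27 read as dates in place of gene names and were left out; they held 0.0206% to 0.0489% of the counts. Rn45s took the largest share of counts, and the widest 95% exact binomial (Clopper-Pearson) interval of such a share spanned 0.105 percentage points. Such intervals cover counting error only. TMM factors were 1.45 and 1.60 in IgG_RIP, 0.790 and 0.846 in Flag_RIP, and 0.782 and 0.827 in HU_Flag_RIP. Replicates correlated across genes (log2 values, Pearson) at 0.981 in mESC, 0.994 in MEF, 0.998 in KD_control, 0.992 in Dppa5a_KD, 0.872 in IgG_RIP, 0.899 in Flag_RIP and 0.856 in HU_Flag_RIP; genes are not independent replicates. Every pair differed by more than sampling noise, with a chi-square per degree of freedom from 1.82 to 12.6.

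Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and all 6 RIP libraries in 1 fit. FPKM values are not counts, so limma 3.58.1 (limma-trend) was used on log2(FPKM + 1) for genes with a mean of at least 1 FPKM in either group; the plan named edgeR for counts and this test for FPKM. DESeq2 1.42.0 was run on the RIP counts as an alternative. Adjusted p-values are Benjamini-Hochberg values, called under 0.05. CPM are counts scaled to the effective library size by edgeR's cpm function. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way. Adjusted p-values of lists are over the lists of 1 comparison. The overlap of RIP and knockdown calls was tested with a one-sided Fisher exact test, also within 3 strata of mean expression. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

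The groups, tests, 32 gene and marker lists, named genes and most alternatives were fixed before the data were examined. A list of 15 mitochondrially encoded genes could not be tested, since none of these symbols were in the tables used here. The genes named were Dppa5a, Rev1 and Polq in every comparison. To these were added genes from the 8 with the largest log2 fold change in each direction, among called genes with a mean of at least 20 CPM (10 FPKM) in the higher group and no overlap between the libraries. Predicted genes, pseudogenes and small RNAs were passed over. For a list with at least 2 called members up to 4 with the smallest p were taken, and for a list with no call at most 2; a part of the genes so chosen is named in the text. Results for 2 of the genes so chosen are withheld and not reported here. The abundant RNAs Rn45s, Rpph1 and Lars2, the macrophage markers and the sex-linked genes were chosen after their values were seen.

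The limma and edgeR fits and camera with the preset correlation were tested on simulated data with 200 changed genes. The other steps were not tested this way. Genes were drawn independently from the fitted spread, so the shares of false calls do not cover trends that many genes share, such as one with transcript length. Of genes changed 2-fold and 4-fold, limma recovered 25.0% and 94.0% for mESC against MEF (11994 genes) and 84.0% and 98.0% for the knockdown (11948 genes), with 4.69% and 5.18% of calls false. Of genes changed 4-fold and 8-fold, edgeR recovered 86.0% and 99.0% for Flag_RIP against IgG_RIP (9771 genes; 4.64% of calls false), 77.0% and 97.0% for HU_Flag_RIP against IgG_RIP (9747 genes; 5.95%), and 83.0% and 99.0% for HU_Flag_RIP against Flag_RIP (9627 genes; 2.15%).

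The alternatives were other scalings, library size alone, no filter or a stricter one on low values, a pseudocount of 0.1, a 2-fold threshold, leaving out the 10 most abundant genes before scaling, other sets of libraries in the fit, a replicate block, DESeq2, and each library left out in turn. Where that left 1 library in a group, it was assumed to vary like the other group or groups.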

Results

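RNA was sequenced in 14 mouse libraries that form 7 groups of 2 libraries each. Embryonic stem cells (mESC), which can give rise to all tissues of the embryo, were compared with embryonic fibroblasts (MEF). Stem cells with Dppa5a knocked down (Dppa5a_KD) were compared with their own control stem cells (KD_control). Dppa5a is a KH-domain RNA-binding protein of pluripotent cells. In RNA immunoprecipitation (RIP), RNA was recovered from stem cells that overexpress Flag-tagged Dppa5a, with a Flag antibody (Flag_RIP), with a Flag antibody after a treatment labelled HU (HU_Flag_RIP), or with control IgG from untreated cells (IgG_RIP). What HU stands for is not given in the labels. The submitters set out to compare splicing among the cell types and the knockdown, and to find the RNAs that Dppa5a binds with and without HU. The tables hold 1 value per gene, so splicing itself could not be tested. The RNA-seq tables give FPKM, the deposited unit, and their confidence bounds correspond to 18332625 to 25337449.5 effective fragments per library. The RIP tables give counts, with totals of 3472020 and 3703236 in IgG_RIP, 13033886 and 9469168 in Flag_RIP, and 9641507 and 7378729 in HU_Flag_RIP. Outside the ribosomal RNA precursor Rn45s, the noncoding RNAs Rmrp and Rpph1, and Lars2, between 702016 and 1492111 counts per library remained. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

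Dppa5a, Rev1 and Polq were followed in every comparison. Rev1 is a scaffold and polymerase of translesion synthesis, which copies past damaged DNA, and Polq is the polymerase of microhomology-mediated end joining. Dppa5a (mm10, chromosome 9, 78367054 to 78368199) was listed at 1485 and 1818 FPKM in the mESC libraries and at 0 and 0.0871 in the MEF libraries. It stood at 5126 and 5417 FPKM in the KD_control libraries and at 101 and 358 in the Dppa5a_KD libraries. The log2 fold change on the log2(FPKM + 1) scale, which is used for all FPKM values and understates the change of low genes, was 10.62 in mESC against MEF (SE 0.22, limma adjusted p = 5.2e-05) and -4.78 in the knockdown (SE 0.63, limma adjusted p = 0.0088). The knockdown libraries differed from each other in the level that remained. Rev1 (chromosome 1, 38052786 to 38129662) had 16.7 and 12.4 FPKM in mESC, 6.45 and 7.44 in MEF, 10.2 and 10.1 in KD_control and 6.28 and 5.45 in Dppa5a_KD. It was higher in mESC (log2 fold change 0.96, SE 0.23, limma adjusted p = 0.017) and lower in the knockdown (-0.70, SE 0.11, limma adjusted p = 0.013). The Rev1 calls ended in some fits with a library left out: without mESC replicate 1 or either MEF library, and without either KD_control library. Such a fit leaves 1 library in a group and takes the spread from the other group, so it does not show that 1 library carries the change. The Rev1 log2 fold change lay between 0.76 and 1.16 in mESC against MEF and between -0.79 and -0.60 in the knockdown over all alternatives. The Rev1 call in the knockdown also ended when FPKM were rescaled to a common sum (adjusted p = 0.11) and when the 10 most abundant genes were left out before scaling (adjusted p = 0.092). Over all alternatives the limma adjusted p of Rev1 ranged from 0.0024 to 0.20 in mESC against MEF and from 1.4e-04 to 0.11 in the knockdown. Polq (chromosome 16, 37011786 to 37095417) did not pass in either comparison, with log2 fold changes of 0.04 (SE 0.20, adjusted p = 0.89) and 0.21 (SE 0.17, adjusted p = 0.39) and levels from 1.99 to 3.36 FPKM in all 8 libraries. Without Dppa5a_KD replicate 2 the Polq value in the knockdown was 0.42, and without replicate 1 it was -0.00464, so it rested on which library was kept.

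**Figure D1:**
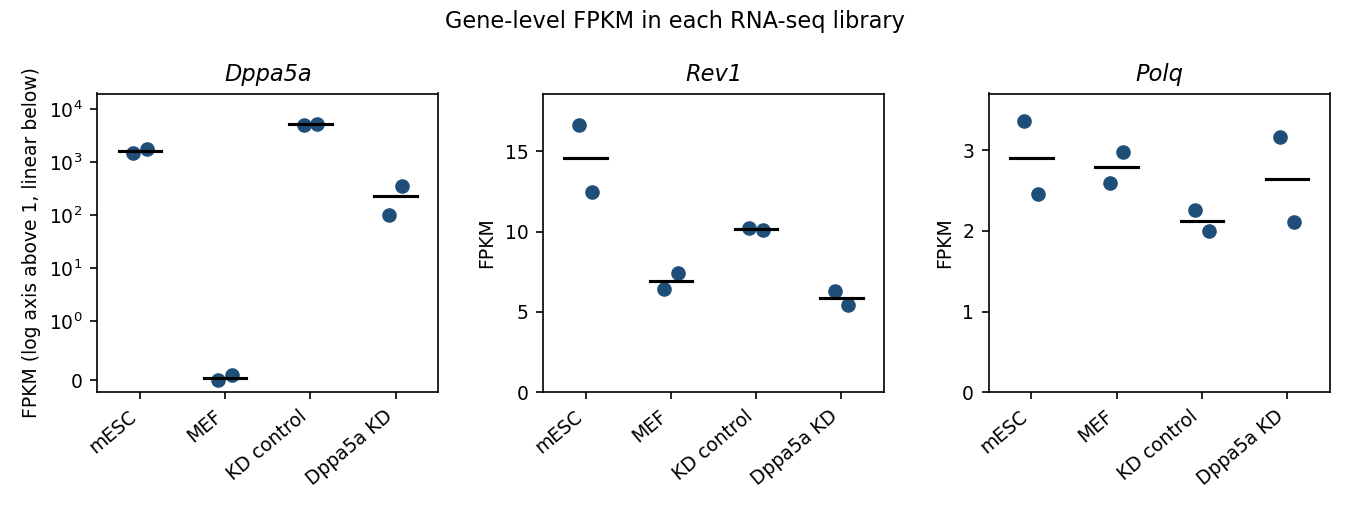
FPKM of Dppa5a, Rev1 and Polq in each RNA-seq library, 1 point per library with a line at the group mean; the Dppa5a axis is logarithmic above 1 and linear below. Dppa5a reached 5126 and 5417 in KD_control and 101 and 358 in Dppa5a_KD, and Rev1 was highest in mESC.

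The listed pluripotency factors were higher in stem cells and the listed fibroblast markers were higher in fibroblasts. All 28 pluripotency factors tested were higher in mESC than in MEF (28 adjusted over the list alone; median log2 fold change 5.95). Pou5f1, the core pluripotency factor, was at 841 ± 225 FPKM (SD, n = 2) in mESC and listed at 0 in both MEF libraries. Zfp42, a marker of naive stem cells, was at 454 ± 68.0 and 0.0284 ± 0.0401 FPKM (log2 fold change 8.78, SE 0.21), and Nanog at 243 ± 4.31 and 0.154 ± 0.0521 FPKM (7.72, SE 0.19). Upp1, a uridine phosphorylase, was among the genes with the largest increase, at 373 ± 82.4 and 0.485 ± 0.0552 FPKM. All 30 fibroblast markers were lower in mESC (30 adjusted over the list alone; median -6.94). The type I collagen gene Col1a1 was at 2560.2 ± 472 FPKM in MEF and 0.456 ± 0.203 in mESC (-10.78, SE 0.25). The proteoglycan Bgn, the matrix glycoprotein Thbs1, the imprinted growth factor Igf2 and the smooth muscle actin Acta2 had log2 fold changes of -10.53, -10.09, -9.90 and -9.87. Sparc, another matrix gene, remained at 164 ± 44.7 FPKM in mESC, against 1188 ± 2.59 in MEF. The stem cells had been kept on feeder fibroblasts and passaged off them before harvest, per the labels. The fibroblast marker median of -6.94 and Col1a1 at 0.456 FPKM in mESC argue against feeder carry-over as the source of the Sparc level there.

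Genes of DNA repair and replication were mostly higher in mESC. Homologous recombination had 16 of 20 members higher (16 adjusted over the list alone), with the nuclease Dna2 (2.87, SE 0.19), the translocase Rad54l (2.20, SE 0.20) and Brca2 (2.27, SE 0.22). The replication stress response had 22 of 28 higher (22 adjusted over the list alone), among them the helicase subunit Mcm2 at 160.3 and 192 against 37.0 and 31.9 FPKM and the single-strand binding protein Rpa2 at 73.3 ± 1.87 against 18.1 ± 0.283. The Fanconi anemia list had 8 of 13 higher (8 adjusted over the list alone), led by Fancd2 (2.64, SE 0.29), and non-homologous end joining had 6 of 12 (6 adjusted over the list alone), with Rif1 (2.68) and the Ku subunit gene Xrcc5 (2.69). In translesion synthesis 9 of 17 members were higher and 1 lower (10 and 1 adjusted over the list alone); the higher ones included Poli at 13.9 ± 2.43 against 1.49 ± 0.154 FPKM, the deubiquitinase Usp7 at 81.5 ± 5.37 against 27.4 ± 2.69, and the sliding clamp Pcna at 335 ± 26.7 against 161 ± 16.3. In microhomology-mediated end joining 5 members were higher and 1 lower of 12 (5 and 1 adjusted over the list alone): Parp1 (2.60, SE 0.29) and Lig1 (1.52, SE 0.28) were higher, and the nuclease subunit Ercc1 was lower (-2.01, SE 0.38).

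The spliceosome core and SR proteins also leaned towards mESC, while cell-type splicing regulators went both ways. In the spliceosome core 15 of 37 members were higher (14 adjusted over the list alone), including Cdc5l (2.04, SE 0.23). Among SR proteins and their kinases 10 of 21 were higher (10 adjusted over the list alone), with Srsf7 at 157 ± 37.6 against 47.9 ± 1.31 FPKM, and among hnRNP proteins 7 of 26 (5 adjusted over the list alone), with Hnrnpf at 586 ± 79.6 against 257 ± 1.45; of all 12875 tested genes 3943 were higher. Cell-type splicing regulators had 5 higher and 6 lower of 16 (5 and 6 adjusted over the list alone; median 0.15). The oocyte and embryo KH-domain complex had all 3 tested members higher (3 adjusted over the list alone), with Ooep at 22.6 ± 2.62 against 0.0475 ± 0.0213 FPKM. Of 10 genes of the two-cell-like state 9 were higher (9 adjusted over the list alone); Zscan4c was at 16.0 and 5.38 FPKM in mESC and listed at 0 in MEF, and values of the near-identical Zscan4 copies are uncertain. Primitive endoderm markers had 9 higher and 2 lower of 12 (9 and 2 adjusted over the list alone), with the laminin Lama1 higher (4.87) and Sparc lower (-2.88). The integrated stress response had 11 of 19 members lower and 1 higher (11 and 1 adjusted over the list alone), with the transcription factor Atf5 (-3.16, SE 0.25) and the serine synthesis enzyme Phgdh (-2.43, SE 0.30) lower. Immediate early genes had 7 lower and 1 higher of 12 (7 and 1 adjusted over the list alone), with Egr1 at 2.41 ± 1.19 FPKM in mESC and 79.0 ± 1.46 in MEF.

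In limma, 7304 of 12875 tested genes differed between mESC and MEF (3943 higher, 3361 lower; 8009 at an unadjusted p under 0.05), and the median over all tested genes was 0.15, so group changes are to be read against that shift. With median-ratio scaling the median was -0.02 and 7144 genes were called, 3298 higher and 3846 lower. In camera with a preset correlation, 14 of 31 lists stood apart from the other genes: pluripotency (adjusted p = 5.1e-14), stem cell markers (3.2e-06), fibroblast markers (7.8e-19), homologous recombination (2.1e-04), replication stress (1.2e-04), Fanconi anemia (0.013), translesion synthesis (0.047), the KH-domain complex (0.026), the two-cell-like state (0.0075), the spliceosome core (0.0033), SR proteins (0.047), the integrated stress response (0.0087), immediate early genes (0.0075) and primitive endoderm markers (0.042). None of the 14 passed with an estimated correlation, where the lowest adjusted p = 0.53. Microhomology-mediated end joining (camera adjusted p = 0.23), non-homologous end joining (0.056) and hnRNP proteins (0.13) did not pass. Without MEF replicate 1 the count fell to 2835 genes and without MEF replicate 2 to 2993, and 9 of the 35 named calls ended in 1 or more such fits: Rev1, Usp7, Pcna, Lig1, Ercc1, Srsf7, Zscan4c, Phgdh and Hnrnpf.

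When Dppa5a was knocked down, messages of some hnRNP and SR splicing proteins rose, and some histone messages fell. Of 26 hnRNP proteins 14 rose (15 adjusted over the list alone; median log2 fold change 0.61), and the other 12 did not pass. Hnrnpm went from 55.6 ± 0.145 to 129 ± 0.348 FPKM (SD, n = 2; log2 fold change 1.19, SE 0.11) and Hnrnph1 from 29.96 ± 0.884 to 67.1 ± 4.61 (1.14, SE 0.11). SR proteins and their kinases moved both ways, with 8 higher and 6 lower of 22 (9 and 7 adjusted over the list alone): Srsf3 (1.64, SE 0.12) and Srsf2 (1.53, SE 0.15) rose, and the SR protein kinase Clk4 fell (-1.33, SE 0.14). In the spliceosome core 4 of 37 members rose (4 adjusted over the list alone), among them Prpf31 (1.01, SE 0.12). Of 22 replication-dependent histone genes 10 fell (11 adjusted over the list alone; median -0.70), with Hist1h1c at 4.06 ± 0.884 against 16.7 ± 0.00700 FPKM. Histone copies are near-identical in sequence, so single histone values are uncertain. Knockdown fold changes also ran with transcript length, with a median of -0.35 in the shortest 10% of genes and 0.06 in the longest 10%. The histone median is to be read against this trend. Ribosomal protein genes had a median of -0.35, with 2 higher and 1 lower of 77. The control libraries stood apart from mESC in the same splicing lists, in a comparison chosen after the data were seen: of 26 hnRNP proteins 14 were lower and 2 higher in KD_control (median -0.74), and of 22 SR proteins and kinases 10 were lower and 2 higher (-0.73), while of 27 histone genes 1 was lower and 2 higher. The rise is therefore relative to control libraries that stood below mESC in these lists. Both comparisons use the KD_control libraries, so such opposite moves arise partly by construction. The mESC libraries are also not a matched baseline: the Y-linked gene Eif2s3y was at 43.2 and 41.2 FPKM in mESC and listed at 0 in all KD_control and Dppa5a_KD libraries.

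Some DNA repair genes changed, in either direction. Of all 12345 tested genes 37.4% were called, 1678 higher and 2940 lower, and the counts of each list are to be read against that share. In translesion synthesis 5 of 17 members fell and 1 rose (5 and 1 adjusted over the list alone; median -0.28). Rev1 fell, as did Primpol, which restarts stalled replication, at 3.94 ± 0.0196 against 6.90 ± 0.0591 FPKM (-0.68, SE 0.10) and Poli at 8.77 ± 0.455 against 13.7 ± 0.491, while Usp7 rose (0.82, SE 0.17). In microhomology-mediated end joining 3 of 12 members rose (3 adjusted over the list alone; median 0.20): the nuclease genes Ercc4 (0.89, SE 0.11) and Fen1 (0.74, SE 0.11) and the ligase Lig3 (0.62, SE 0.13). Polq itself did not pass. Homologous recombination had 6 members lower and 1 higher of 20 (6 and 1 adjusted over the list alone), with Rad54b (-0.75, SE 0.10) among those lower; the list median was -0.11 and turned to 0.03 with rescaling to a common sum. Non-homologous end joining had 3 members higher and 0 lower of 12 (3 and 0 adjusted over the list alone), Fanconi anemia 0 and 1 of 13 (0 and 0), and the replication stress response 1 and 0 of 28 (0 and 0). Among p53 targets 7 fell and 2 rose of 24 (8 and 2 adjusted over the list alone), with the cell death gene Bbc3 (-1.21, SE 0.15) and the damage-recognition gene Ddb2 (-1.21, SE 0.12) lower. After rescaling to a common sum, translesion synthesis had 1 member lower and 1 higher, and the calls of Rev1, Primpol, Poli, Lig3 and Rad54b ended.

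Pluripotency factors went in both directions, with 7 higher and 3 lower of 28 (7 and 3 adjusted over the list alone; median 0.28). The threonine dehydrogenase Tdh (2.26) and the LINE-derived L1td1 (2.24) rose, and Fbxo15 (-2.53) and Dppa3 (-1.71) fell, each with an SE of 0.10 to 0.14. Some lineage markers changed, though none of these lists passed camera: trophectoderm had 6 lower and 1 higher of 8 (6 and 1 adjusted over the list alone), with the keratin Krt18 at 5.20 ± 0.163 against 15.4 ± 0.442 FPKM and Tfap2c at 9.64 ± 1.35 against 22.3 ± 0.0738; primitive endoderm 6 lower and 1 higher of 9 (6 and 1 adjusted over the list alone), with Amn (-1.26) and Gata4 (-1.06). Mesoderm and endoderm had 5 lower and 3 higher of 13 (6 and 3 adjusted over the list alone), formative and primed pluripotency 5 lower and 2 higher of 14 (6 and 4), and neural ectoderm 0 lower and 1 higher of 4 (0 and 2). Fibroblast markers fell in 8 of 12 tested (8 adjusted over the list alone; median -0.70), with the protease Mmp2 at 3.52 ± 0.556 against 12.6 ± 1.29 FPKM and the receptor Pdgfrb at 2.56 ± 0.345 against 7.75 ± 0.200. The genes with the largest increases included the Toll-like receptor adaptor Tril (3.35, SE 0.15), the homeobox gene Gbx2 (3.07, SE 0.11), Myc (2.78, SE 0.12), Aard (2.77) and the FGF feedback gene Spry4 (2.41). The largest decreases besides Dppa5a included Hist3h2ba (-3.24, SE 0.26), the snoRNA host gene Snhg12 (-3.20, SE 0.59), the stress transcription factor Ddit3 (-3.15, SE 0.33), the enolase Eno2 (-2.81) and the germ cell gene Stra8 (-2.77). The integrated stress response list, which holds Ddit3, had 6 members higher and 3 lower of 19 (6 and 3 adjusted over the list alone), with a median of 0.32. In the glycolysis list 3 genes fell and 1 rose of 16 (3 and 1 adjusted over the list alone), with the glucose transporter Slc2a3 at 629 ± 21.1 against 1571 ± 3.34 FPKM and Bnip3 at 93.1 ± 3.19 against 289 ± 2.44. In the comparison with mESC chosen after the data were seen, KD_control stood apart in several of these lists too: 11 of 24 p53 targets were higher and 2 lower in KD_control (median 0.56), 11 of 16 glycolysis genes higher (2.03), 6 of 13 fibroblast markers higher and 1 lower (1.10), 3 of 9 trophectoderm markers higher (0.72) and 9 of 12 primitive endoderm markers lower (-1.56). Decreases called in the p53 target, glycolysis, fibroblast and trophectoderm lists are therefore relative to control libraries that stood above mESC in part of them. In the knockdown the p53 target and glycolysis lists did not pass camera with a preset correlation (adjusted p = 0.29 and 0.31). Of all 12345 tested genes 2940 were lower. As the KD_control libraries are in both comparisons, such opposite moves arise partly by construction. Actb, often used as a control gene, was at 1646 and 994 FPKM in the knockdown and 383 and 378 in the control libraries (1.75, SE 0.30).

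In limma, 4618 of 12345 tested genes changed in the knockdown (1678 higher, 2940 lower; 6131 at an unadjusted p under 0.05), and 1092 of them by at least 2-fold (305 higher, 787 lower). The median over all tested genes was -0.11. The split moved with scaling and level: 4513 genes (1932 higher, 2581 lower) with median-ratio scaling, 3194 (1319 higher, 1875 lower) after rescaling to a common sum, and 6421 (3227 higher, 3194 lower) with both the trend with length and the average level of each library removed. With the trend alone removed the share of lower genes stayed near that reported, at 6327 calls (2362 higher, 3965 lower). Replicate differences followed length in Dppa5a_KD (Spearman correlation across genes 0.68; genes are not independent replicates) and little in KD_control (0.05). In camera with a preset correlation, 6 of 30 lists passed: hnRNP proteins (adjusted p = 1.2e-04), histones (0.011), pluripotency (0.032), fibroblast markers (0.037), the spliceosome core (0.041) and microhomology-mediated end joining (0.043). None passed with an estimated correlation (lowest adjusted p = 0.78), and translesion synthesis did not pass camera (adjusted p = 0.69). The count was 2440 and 2415 without KD_control replicate 1 or 2, 8593 and 9436 without Dppa5a_KD replicate 1 or 2, and 9 of the 42 named calls ended in 1 or more such fits: Rev1, Primpol, Poli, Usp7, Fen1, Lig3, Rad54b, Slc2a3 and Actb. With all 8 RNA-seq libraries in the fit those of Fen1, Bbc3, Krt18, Amn and Bnip3 ended.

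**Figure D2:**
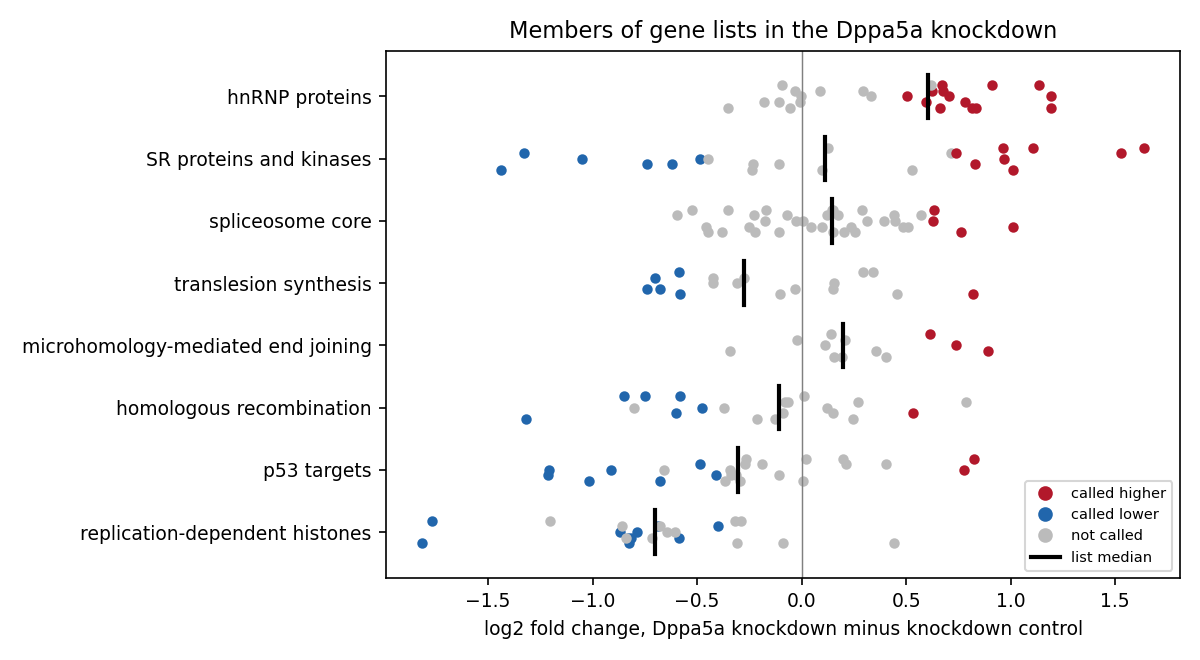
Log2 fold change (Dppa5a_KD minus KD_control, on the log2(FPKM + 1) scale) of each tested member of 8 gene lists, with colours for called higher, called lower or not called and a bar at the list median. The medians were 0.61 for hnRNP proteins and -0.70 for histones.

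Flag immunoprecipitates were compared with IgG immunoprecipitates to ask which RNAs are recovered more with the Flag antibody. The RNAs higher with Flag included some of the two-cell-like state, some of histones and some of SR and hnRNP proteins, and those lower included some macrophage and stress genes. Slc29a1, a nucleoside transporter, was at 44.3 ± 8.57 CPM (counts scaled to the effective library size; SD, n = 2) in Flag_RIP and 2.21 ± 0.253 in IgG_RIP (log2 fold change 4.32, SE 0.40, edgeR adjusted p = 2.6e-06). Of 15 genes of the two-cell-like state 8 were higher (12 adjusted over the list alone; median 3.22), with Zscan4f (3.99, SE 0.51) and Zscan4d (3.21, SE 0.60), near-identical copies whose single values are uncertain. Of 30 histone genes 11 were higher (18 adjusted over the list alone; median 1.06), including Hist1h3d (3.22), Hist1h3e (2.44) and Hist1h1d (2.05). Among SR proteins and kinases 3 of 21 were higher (4 adjusted over the list alone): Srsf5 at 109 ± 0.761 against 22.9 ± 2.23 CPM, Srsf7 (1.45, SE 0.35) and Tra2a (1.495, SE 0.37). Among hnRNP proteins 2 of 26 were higher (5 adjusted over the list alone), Hnrnpa2b1 (1.53, SE 0.29) and Hnrnph1 (1.55, SE 0.35). Scaled by library size alone, where the median of all genes was -0.87, the medians of SR and hnRNP lists turned from 0.64 and 0.58 to -0.26 and -0.33, and the calls of Srsf7, Tra2a, Hnrnpa2b1 and Hnrnph1 ended, as did that of Malat1. Fbxo15 (2.87, SE 0.36), Slc2a3 (2.15, SE 0.26) and the nuclear noncoding RNA Malat1 (1.36, SE 0.34) were also higher.

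Lower with Flag than with IgG were the macrophage lysozyme Lyz2 at 3.31 and 4.12 against 99.2 and 40.1 CPM (-4.23, SE 0.53), the chemokine Ccl6 (-3.88, SE 0.62), the RNA-binding protein Rbm47 (-3.73, SE 0.41), Wwc1 (-2.93) and the antiviral protein Zc3hav1 (-2.76). The integrated stress response had 4 of 19 genes lower (8 adjusted over the list alone; median -0.96), among them Nupr1 (-2.76, SE 0.48) and Chac1 (-1.68, SE 0.36). The naive pluripotency factor Tfcp2l1 (-1.65, SE 0.32) and the signalling factor Bmp4 (-3.06, SE 0.53) were lower as well. The summed level of 55 macrophage markers, listed after the Lyz2 result was seen and before their own values were, was 109 and 58.9 CPM in IgG_RIP, 15.5 and 18.1 in Flag_RIP, and 17.5 and 49.6 in HU_Flag_RIP. The 70 tested genes of the 5 DNA repair lists had 0 edgeR calls, with 9 at an unadjusted p under 0.05 and 1 DESeq2 call. Sprtn, a protease of translesion synthesis, was at 5.06 and 3.499 CPM in Flag_RIP and 1.19 and 0 in IgG_RIP (adjusted p = 0.11), and the ligase Rad18 at 5.06 and 7.37 and 2.79 and 2.03 (adjusted p = 0.26). Dppa5a RNA was at 169.6 and 160.2 CPM in Flag_RIP and 232 and 252 in IgG_RIP (-0.55, SE 0.24, adjusted p = 0.25); with library size alone it was -1.46 and passed (adjusted p = 9.4e-04; range over all alternatives up to 0.57). Rev1 had 0.73 (SE 0.49, adjusted p = 0.52) on 13 and 41 counts in IgG_RIP and 66 and 77 in Flag_RIP, and Polq 0.12 (SE 0.64, adjusted p = 0.96); neither difference was detectable at this depth.

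The immunoprecipitates were dominated by a few RNAs. Rn45s took 43.6% ± 6.07 of the counts in IgG_RIP, 72.9% ± 0.372 in Flag_RIP and 68.2% ± 1.72 in HU_Flag_RIP (SD, n = 2), and Rmrp, the RNA of RNase MRP, 31.9% ± 5.21, 8.19% ± 0.258 and 14.2% ± 1.94. Rmrp was lower in Flag_RIP relative to the other genes (-1.06, SE 0.09, edgeR adjusted p = 1.8e-06).

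In edgeR, 243 of 10473 tested genes differed between Flag_RIP and IgG_RIP (121 higher, 122 lower; 1607 at an unadjusted p under 0.05). With library size alone as the scale 2278 genes differed, 64 higher and 2214 lower, and the ribosomal protein Rpl13, called higher with 0.86, had -0.03. In camera with a preset correlation, 6 of 30 lists passed: the two-cell-like state (adjusted p = 1.9e-14), histones (3.4e-19), the integrated stress response (3.5e-08), hnRNP proteins (2.5e-07), SR proteins (4.8e-06) and ribosomal proteins (0.003; 1 of 74 higher, median 0.22, which was -0.67 with library size alone). None passed with an estimated correlation (lowest adjusted p = 0.39). Without IgG_RIP replicate 1 or 2 only 30 and 48 genes were called, and of the 25 named calls 12 ended without the one and 12 without the other; 10 held without each library in turn, among them Slc29a1, Zscan4f, Hist1h3d, Fbxo15, Srsf5, Lyz2 and Rbm47.

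After HU, the RNAs higher in the Flag immunoprecipitate than in IgG included some p53 targets, and some histone RNAs were lower. Both the antibody and the treatment differ in this comparison, since the IgG libraries are from untreated cells. Of 24 p53 targets 7 were higher (14 adjusted over the list alone; median 1.39), with the cyclin Ccng1 at 74.6 ± 12.6 against 12.7 ± 4.56 CPM (SD, n = 2; 2.56, SE 0.35), Trp53inp1 (2.31, SE 0.33), the cell death gene Pmaip1 (2.47, SE 0.36) and the antiproliferative gene Btg2 (2.48, SE 0.38). Of 30 histone genes 12 were lower (18 lower and 1 higher adjusted over the list alone; median -1.03), with Hist1h2bk (-2.87, SE 0.37) and Hist1h1b (-1.95, SE 0.33). The two-cell-like state had 8 of 15 genes higher (12 adjusted over the list alone), with Zscan4f (3.29) and Zscan4d (3.15), SR proteins 4 of 21 (6 adjusted over the list alone), with Srsf5 (2.09), and hnRNP proteins 2 of 26 (4 adjusted over the list alone), with Hnrnpa2b1 (1.29). The integrated stress response had 3 of 19 lower (7 adjusted over the list alone), with Chac1 (-2.78, SE 0.39) and Nupr1 (-2.14, SE 0.47). Pluripotency factors had 2 lower and 1 higher of 27 (5 and 1 adjusted over the list alone): Tfcp2l1 (-1.84) and Utf1 (-1.29) were lower and Fbxo15 (2.37) higher. Slc29a1 (3.95, SE 0.39), the germ cell gene Dazl (4.22, SE 0.77; 33.9 and 10.0 CPM in the HU_Flag_RIP libraries), the lactate dehydrogenase Ldhb (3.68) and the nuclear noncoding RNA Neat1 (1.78) were higher, and Rbm47 (-4.09, SE 0.43) and Reep6 (-2.92, SE 0.39) lower.

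Dppa5a RNA was lower in HU_Flag_RIP than in IgG_RIP, at 114 and 114 against 232 and 252 CPM (-1.08, SE 0.24, edgeR adjusted p = 0.017). Rev1 did not pass (1.64, SE 0.49, adjusted p = 0.075; 13 and 41 counts against 115 and 90; adjusted p = 0.035 with no filter on low counts, and 0.015 to 0.42 over all alternatives), nor did Polq (0.68, SE 0.64, adjusted p = 0.65). In edgeR, 300 of 10473 genes differed (151 higher, 149 lower; 1788 at an unadjusted p under 0.05), and 2709 with library size alone (92 higher, 2617 lower), where the median of all genes was -0.88 and the medians of SR and hnRNP proteins turned to -0.46 and -0.51, that of ribosomal proteins from 0.22 to -0.71, and the calls of Hnrnpa2b1 and Neat1 ended. The 70 repair genes had 0 edgeR calls, with 13 at an unadjusted p under 0.05 and 2 DESeq2 calls. In camera with a preset correlation, 8 of 30 lists passed: histones (adjusted p = 7.2e-13), the two-cell-like state (1.3e-10), p53 targets (5.2e-10), the integrated stress response (2.0e-06), SR proteins (8.9e-04), hnRNP proteins (5.2e-04), ribosomal proteins (8.9e-04) and pluripotency (0.023). None passed with an estimated correlation (lowest adjusted p = 0.44). Without IgG_RIP replicate 1 or 2 only 30 and 23 genes were called, and without HU_Flag_RIP replicate 1 186; of the 22 named calls 12 ended without IgG_RIP replicate 1 and 17 without replicate 2, and those of Slc29a1, Rbm47, Reep6, Hist1h2bk and Chac1 held without each library in turn. The Dppa5a call ended without any 1 of the 4 libraries, with adjusted p from 6.6e-05 to 0.18 over all alternatives. The comparisons of Flag_RIP and of HU_Flag_RIP share the IgG libraries, and 79 genes were higher and 71 lower in both. Unchanged groups simulated against the shared controls gave 0 of either kind in 20 draws, and independent lists would share 1.74. The correlation of their log2 fold changes across genes was 0.80 against a simulated 0.52, and the covariance 1.16 against 0.239, a difference of 0.922. The controls were not split, since each comparison would keep only 1 of them. The simulation holds the shared controls with random spread around equal levels only, so a trait that both IgG libraries share may still be part of the excess.

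Between the Flag immunoprecipitates with and without HU, most histone RNAs tested were lower and some p53 target RNAs higher after HU. Of 30 histone genes 27 were lower (all 30 adjusted over the list alone; median -2.14), and they made up 27 of the 49 genes called lower. Hist1h2bk went from 73.6 ± 20.3 CPM (SD, n = 2) to 7.37 ± 3.28 (-3.33, SE 0.38), Hist1h2ak from 63.8 ± 15.0 to 7.72 ± 2.79, and Hist1h2bc from 56.3 ± 17.4 to 7.04 ± 0.196. Histone genes outside the list were called lower too, among them Hist1h2bh, Hist1h2bm and Hist3h2a, the last from 45.6 ± 24.8 to 4.19 ± 0.107 CPM. Of 24 p53 targets 6 were higher (13 adjusted over the list alone; median 1.25): Ccng1 (2.08, SE 0.33, edgeR adjusted p = 0.0022), Trp53inp1 (2.05, SE 0.32) and Btg2 (2.20, SE 0.37) were higher, as were the p53 ubiquitin ligase gene Mdm2 (1.63), Phlda3 (2.44) and the cell cycle inhibitor Cdkn1a (2.28). Zfp365 (2.55, SE 0.53), Cep170b (1.78), Lyz2 (2.50, SE 0.51; 9.70 and 32.7 against 3.31 and 4.12 CPM) and Rmrp (0.82, SE 0.09) were higher too. Pluripotency factors had 0 edgeR calls of 27, with 0 at an unadjusted p under 0.05 and 0 DESeq2 calls, and a median of -0.39; Esrrb was at 71.6 and 47.1 against 105 and 74.5 CPM and Nanog at 70.0 and 38.8 against 85.0 and 74.6. The 70 repair genes had 0 edgeR calls, with 1 at an unadjusted p under 0.05 and 0 DESeq2 calls. The nucleotide reductase subunit Rrm2 had 0.77 (adjusted p = 0.94) and the stress gene Sesn2 1.27 (adjusted p = 0.13; 0.048 without HU_Flag_RIP replicate 2 and 0.039 in DESeq2). Dppa5a (-0.53, SE 0.24), Rev1 (0.91, SE 0.46) and Polq (0.56, SE 0.62) did not pass, each with an adjusted p = 1.

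In edgeR, 64 of 10473 genes differed with HU (15 higher, 49 lower; 415 at an unadjusted p under 0.05). In camera with a preset correlation, 4 of 30 lists passed: histones (adjusted p = 6.2e-114), p53 targets (1.6e-24), pluripotency (1.0e-05) and stem cell markers (0.0041; median -0.37). None passed with an estimated correlation, with histones and p53 targets at an adjusted p = 0.14 and the other 2 lists at 0.45. No input or HU-treated IgG library was analysed here, so changes in the RNA level of the cells and changes in recovery cannot be separated. Of the 14 named calls 8 held without each library in turn, and those of Zfp365, Lyz2, Cdkn1a, Cep170b, Mdm2 and Phlda3 ended without 1 or more libraries. With only the 2 groups compared, 41 genes were called and the calls of Zfp365, Lyz2, Cdkn1a, Cep170b and Mdm2 ended.

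**Figure D3:**
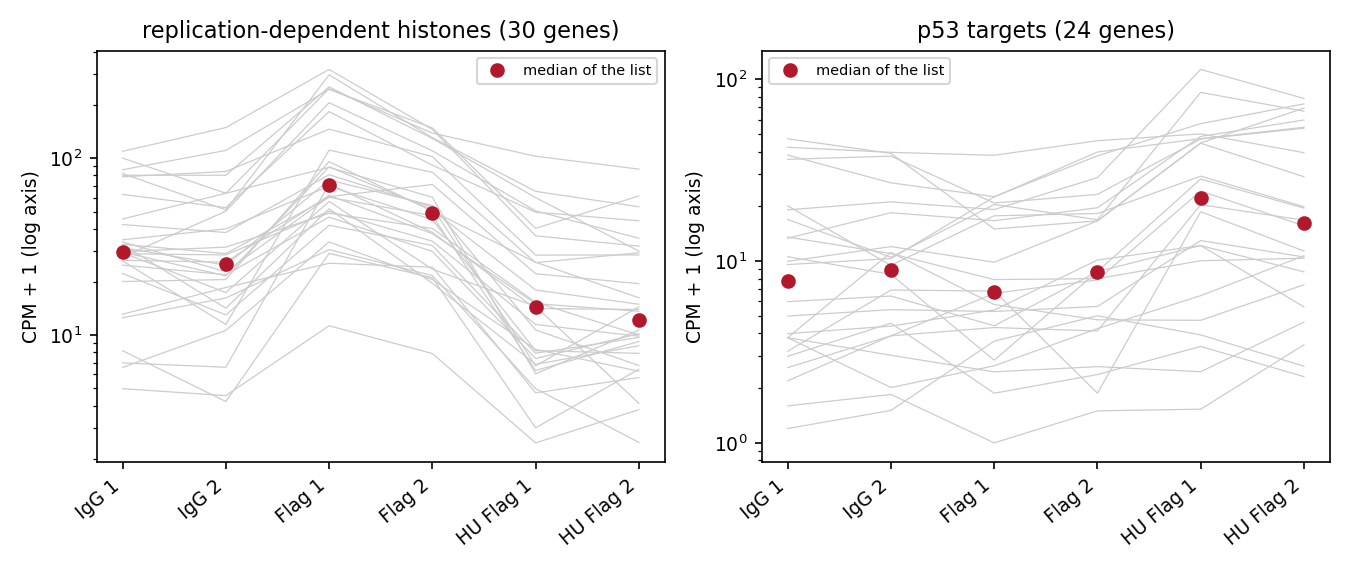
CPM + 1 on a logarithmic axis for each of 30 histone genes and 24 p53 targets in the 6 RIP libraries, with 1 thin line per gene and a point at the list median of each library. Histone medians fell from Flag_RIP to HU_Flag_RIP (median log2 fold change -2.14), and p53 target medians rose (1.25).

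Genes called in Flag_RIP against IgG_RIP were then set against genes that changed when Dppa5a was knocked down. Of 109 genes higher in Flag_RIP than IgG_RIP and tested in both comparisons, 53 changed in the knockdown, against 36.4 by chance (odds ratio 1.90, 95% interval 1.28 to 2.82, one-sided Fisher exact p = 0.00068; 2.01 as a common odds ratio over 3 strata of mean expression). They were lower in the knockdown more often than by chance (36 against 20.0; odds ratio 2.21, Fisher exact p = 0.00017, 0.00034 adjusted over 6 tests), and higher in 17 against 16.4 (odds ratio 1.04). Of 105 genes lower in Flag_RIP, 49 were higher in the knockdown against 15.8 by chance (odds ratio 5.07, Fisher exact p = 1.1e-14), and 8 were lower against 19.3 (odds ratio 0.36). Fbxo15 was higher in Flag_RIP (2.87) and lower in the knockdown (-2.53), Slc2a3 likewise (2.15 and -1.32), and Hnrnph1 higher in both (1.55 and 1.14). The Fisher test takes genes as independent, while near-identical copies such as Hist1h3b and Hist1h3c, or the Zscan4 genes, were counted as separate genes.

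**Figure D4:**
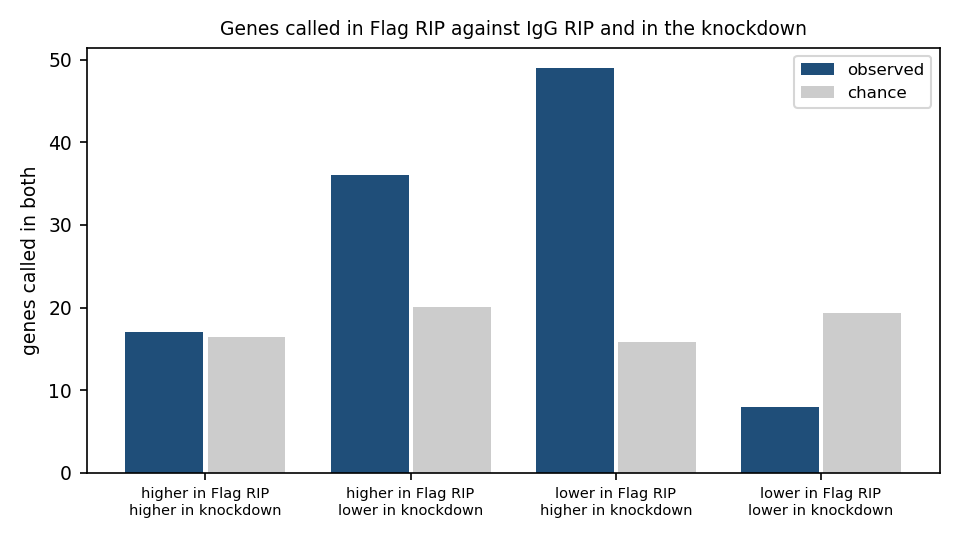
Number of genes called in Flag_RIP against IgG_RIP that were also called higher or lower in the knockdown (dark bars), beside the number expected by chance (light bars). Genes lower in Flag_RIP and higher in the knockdown numbered 49 against 15.8 by chance.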

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

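The tests of feeder carry-over and of recovery with Dppa5a were chosen only after their results were seen, and the markers of the macrophage test were listed after the Lyz2 result, in place of 26 markers whose values had already been seen. The split of the length test into trend and level was made after both had been removed together and that result seen.

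A difference between the groups with and without HU drew attention to a pair of lists: the median log2 fold change of p53 targets in HU_Flag_RIP against Flag_RIP was 1.25 (edgeR fit), and that of replication-dependent histones was -2.14.

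Macrophage genes were higher in IgG_RIP than in Flag_RIP: Lyz2 had 498 and 237 counts in IgG_RIP and 34 and 33 in Flag_RIP, Laptm5 20.9 and 18.6 CPM against 4.08 and 5.37, and Ctss 13.7 and 5.59 CPM in IgG_RIP. Lower depth of the IgG libraries is argued against, since these raw Lyz2 counts were higher in IgG_RIP despite its lower totals. With all libraries thinned to 1 effective depth Lyz2 had a log2 fold change of -4.02. Thinning keeps the expected ratio, so that value adds little. Carry-over of collagen-making feeder fibroblasts is argued against by a ratio of Col1a1 to Lyz2 of 0 in both IgG_RIP libraries, against 103 and 68.3 in MEF. The MEF libraries themselves held Lyz2 at 28.1 and 32.6 FPKM. The ratio therefore does not exclude macrophage-type cells that came with a fibroblast preparation. Cells of a macrophage type in the IgG preparations may be a source, as a hypothesis: 55 further markers summed to 3.25 times as much in the lower IgG_RIP library as in the higher Flag_RIP library, while Tyrobp had 12 and 1 counts. The labels name no such cells, HU_Flag_RIP replicate 2 also held 49.6 CPM of these markers, and besides the mixed cells, depth and feeders no explanation was tested; the groups give no biological one.

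Genes lower in Flag_RIP than IgG_RIP were often higher in the knockdown, and genes higher in Flag_RIP often lower. Recovery of bound RNAs that fall with Dppa5a, taken alone, was set to predict no excess in the former overlap. That overlap had an odds ratio of 5.07 against 2.21 for the latter. Both comparisons are scaled relative to the other genes, so RNAs bound little could be called lower with Flag and higher in the knockdown. The former overlap therefore does not decide against recovery. Expression level is argued against as the whole cause, with common odds ratios over 3 strata of mean expression of 4.69 and 2.61. For genes higher in Flag_RIP recovery stays open too, since the other overlap was the larger one and a common cause was not excluded. The remaining explanations, recovery of bound RNAs and a difference in cell state, cannot be told apart. For the latter, genes lower in Flag_RIP overlapped genes higher in KD_control than mESC with an odds ratio of 1.88 (one-sided Fisher exact p = 0.0019, 0.0077 adjusted over 4 tests) and genes higher in Flag_RIP overlapped genes lower there with 1.68 (adjusted p = 0.032), short of the 2 set in advance.

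More genes were called lower than higher in the knockdown, 63.7% of those called. That share was 62.7% with the trend of each library with length removed and its average level kept. This setting keeps any shift in average level, which the share also follows, so it does not decide whether transcript length is the cause. Whether the libraries differ in overall level is left open. Centring the level of each library brings the share near even by construction (51.4% with the trend kept, 49.7% with both removed) and so decides nothing, and the share was 57.2% with median-ratio scaling and 58.7% after rescaling to a common sum. A technical difference in level and a change in the cells cannot be told apart, since FPKM hold no outside standard.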

How the results depend on the processing

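The crossed pairing, the removal of length trend and average level together and the thinned counts were chosen after seeing the data; the other alternatives were planned. The knockdown of Dppa5a held under all alternatives run, from -5.69 to -3.88 when libraries were left out. The overlap of genes higher in Flag_RIP with knockdown calls held in the few settings tried. Its odds ratio was 1.93 at 2-fold, 2.15 with a replicate block and, with length trend and average level both removed, 1.45 with a Fisher exact p = 0.035. Genes higher in HU_Flag_RIP than IgG_RIP, taken in their place, gave 2.04. The overlap was not rerun with a library left out or with other scalings. Counts of called genes moved by over 1.5 times as follows; the 2-fold threshold keeps only a part of the calls by construction and the mean of at least 5 FPKM tests fewer genes, and other causes were not tested. In the knockdown, 3023 genes were called with a mean of at least 5 FPKM, 1092 at 2-fold and 2992 with all 8 libraries in the fit. For Flag_RIP and HU_Flag_RIP against IgG_RIP, 2278 and 2709 were called with library size only, 433 and 532 with no filter on low counts, and 508 and 617 with a replicate block. With only the 2 groups compared, HU_Flag_RIP against Flag_RIP gave 41. Leaving out each library in turn gave 2835 to 7056 genes for mESC against MEF, 2415 to 9436 for the knockdown, 30 to 248 for Flag_RIP and 23 to 252 for HU_Flag_RIP against IgG_RIP, and 44 to 71 between the Flag groups. The lowest counts came without MEF replicate 1 (2835; without replicate 2, 2993), KD_control replicate 2 (2415; without replicate 1, 2440), IgG_RIP replicate 1 (30; without replicate 2, 48) and IgG_RIP replicate 2 (23; without replicate 1, 30; without HU_Flag_RIP replicate 1, 186). The highest knockdown counts came without 1 of the Dppa5a_KD libraries. There the spread is taken from the KD_control pair alone, the closest of the pairs (chi-square per degree of freedom 1.82).

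Directions reversed for Polq in mESC against MEF with median-ratio scaling (-0.10), without mESC replicate 1 (-0.13) and without MEF replicate 1 (-0.03; the highest without a library was 0.21, without mESC replicate 2, and over all alternatives 0.23, with length trend and average level removed), for Polq in the knockdown without Dppa5a_KD replicate 1 (-0.00464, against 0.42 without replicate 2), and with library size only for Rev1 (-0.18), Polq (-0.77) and Rpl13 (-0.0316) in Flag_RIP and Polq (-0.23) in HU_Flag_RIP against IgG_RIP; of these only Rpl13 was called. DESeq2 called 343, 419 and 72 genes in the 3 RIP comparisons, and thinning to 1 effective depth 193, 230 and 53. Of 38 list calls, 0 held with an estimated correlation in camera and 16 in fry. The former test has little power with 2 libraries per group, so its failures do not argue against a list. DESeq2 was not run on FPKM, which are not counts.

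The replicate numbers are shared between groups, but the labels do not say that they mark a shared culture or day. The correlation of deviations of same-numbered libraries was -0.54, 0.01, -0.01, -0.03 and 0.36 in the 5 comparisons. With a replicate block 6408 genes were called for mESC against MEF, 5296 in the knockdown and 86 between the Flag groups, and with crossed numbers 8950 for mESC against MEF. The Pcna call in mESC against MEF ended with the replicate block. The RIP libraries held as few as 702016 counts outside the 4 most abundant RNAs, and genes with few counts such as Rev1 and Polq had wide errors.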

Other observations

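The comparisons in this part were all chosen only after the data were seen. KD_control and mESC, both labelled wild-type stem cells, differed widely. In limma, 5220 of 12595 genes differed (3336 higher and 1884 lower in KD_control), against 1683 of 12068 (971 higher, 712 lower) between Dppa5a_KD and mESC. These counts do not rank the groups by distance from mESC, since replicates were closer in KD_control than in Dppa5a_KD (chi-square per degree of freedom 1.82 and 3.31). Replicate differences also followed length in Dppa5a_KD (Spearman correlation 0.68) and mESC (0.35). Of 18 genes of the integrated stress response 14 were higher in KD_control (median log2 fold change 2.193), and of 16 glycolysis genes 11 were higher (2.03). Of 24 p53 targets 11 were higher and 2 lower (0.56). Of 26 hnRNP proteins 14 were lower and 2 higher (-0.74), of 22 SR proteins and kinases 10 lower and 2 higher (-0.73), and of 12 primitive endoderm markers 9 were lower (-1.56). KD_control is also the control of the knockdown comparison, so lists that move one way here and the other way in the knockdown do so partly by construction. The labels do not say that these libraries came from the same line or were made together.

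The Y-linked genes Ddx3y and Eif2s3y were listed at 15.8 and 14.7 and at 43.2 and 41.2 FPKM in the mESC libraries and at 0 in all KD_control and Dppa5a_KD libraries, as were Kdm5d and Uty. Xist, the noncoding RNA of X inactivation, was at 20.8 and 26.0 FPKM in MEF and at 1.27 and 0.849 in mESC. Between the Dppa5a_KD libraries the difference of replicate 1 and 2 ran with transcript length, with a median of -0.62 on the log2 scale in the shortest 10% of genes and 0.33 in the longest 10%; the median FPKM of 77 ribosomal protein genes was 960 and 1640 in these libraries and 1519 and 1560 in KD_control.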
